A study of Mus musculus with 5 samples.

How the data were processed

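RNA from splenic B cells (2 samples) and liver (3 samples) of C57BL/6 mice was measured on 1-colour Agilent whole mouse genome arrays, 1 sample per array. Groups and replicate numbers were taken from the labels. The deposited scanner files hold intensity values that were made with Agilent Feature Extraction 9.5.3.1, per the submitters' processing notes. Per the file headers, the processed signal is a background-subtracted intensity with spatial detrending, and spots not above background carry a substitute value. These intensities are not scaled between arrays. The deposited series table holds the authors' log2 values of the same arrays, whose processing is not given in the sources used here. Each of its columns correlated with the log2 processed signal of its own array at 0.993 to 0.9996 over 41174 probes, with medians of 4.03, 4.04, 4.00, 3.98 and 4.00 for B cells 1 and 2 and livers 1 to 3. All 5 columns share a minimum of 1.63 and a maximum of 18.6, so the scale is log2 and the values are not centred, and as single-channel values they have no direction. That table was used as an alternative only.

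Each array had 43379 gene spots after control spots were left out, for 41174 probes, of which 245 were spotted more than once and averaged. Outlier flags on at least 1 array removed 10 probes, counted before the filter on signal, while saturated spots stayed (1 spot, in liver 1). Log2 of the processed signal minus the array's 75th percentile over gene spots was used. A probe was called well above background where at least 0.5 of its spots carried that flag. It was tested if it was well above background on every array of at least 1 group, which left 22169 probes. Probes were named through their accession (22944), symbol (6664) or synonym (3108) in a RefSeq gene table (assembly GRCm38.p6), and the other 8458 kept the name in the file. The name changed for 8247 probes, and the array held 27670 genes, 19504 of them in the table. Probe positions are those of the array design on mm7 (NCBI35), per the file headers. A gene was represented by its tested probe with the highest mean over the 5 arrays, giving 15602 tested genes, of which 4952 had more than 1 tested probe.

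Differences between tissues were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with the package data.table (version 1.17.8), with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. A gene was counted as detected in a tissue if any of its probes was well above background on every array of it. For 36 gene lists fixed before the data were examined, limma's camera was run with its preset correlation of 0.01 on the 34 lists with at least 5 tested members, and repeated with an estimated correlation and with fry. Fry tests whether a list's genes move one way and does not compare them with other genes. Where a gene's probes were below background on all arrays of a group, an at-least fold was given in place of a fold. The same was done, after the data were seen, for named genes with signal on part of a group's arrays. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays limits the precision: the median SD over genes was 0.14 log2 units between B cell arrays and 0.24 between liver arrays.

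Genes were named by a rule written before the data were examined. It took the 8 genes with the largest difference in each direction among called genes measured on all 5 arrays with groups that did not overlap, and the 4 with the largest at-least fold in each direction, both among genes with an official symbol. Of each list it took up to 4 called members with the largest difference, up to 2 called the opposite way and up to 2 brightest members not called. Cd19 and Alb were fixed by hand. Genes of the pancreas, gut and other tissues and gene families were looked at after the data were seen, and the pancreas and gut marker lists were written after some of their genes had been seen. Markers of islets, stomach, kidney, skeletal muscle, lung, brain, adipose tissue and testis were written with them.

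The fit was tested on simulated data for the comparison of B cells with liver, with the 15602 genes and 200 of them changed. It called 58.2% of genes changed by 1.5 log2 units, 91.0% of those changed by 2 and 92.4% of those changed by 3, with 4 false calls. In the real fit 65.5% of the tested genes were called, so these rates do not carry over to it. By camera, a simulated list of 20 genes shifted by 2 had adjusted p = 7.4e-49 with the preset correlation and adjusted p = 0.00104 with an estimated correlation. An unshifted list had adjusted p = 0.913 with the preset correlation. The simulated noise was independent between genes and most genes were unchanged, so the list tests on the real data can behave otherwise.

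The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, scaling to the median, 2 other filters on dim probes, the mean of a gene's probes, leaving out saturated probes, the series table, the replicate number as a block, trend and robust variance settings, each array left out in turn, other fold minimums and other detection rules. Added after the data were seen were scaling to the spike-ins, a percentile over probes measured on all arrays, a common detection floor, and a fit without livers 2 and 3. Promoter CpG classes were planned, and not run because no genome was used here.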

Results

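Gene expression was compared between B lymphocytes and liver of C57BL/6 mice, an inbred laboratory strain. B cells were taken from spleen with magnetic beads against CD19, a surface protein of the B lineage, and liver was dissected, washed and frozen. Total RNA (500 ng per array) was labelled with the green dye Cy3 and hybridised to 1-colour oligonucleotide arrays covering the mouse genome. There were 5 arrays, 2 of B cells and 3 of liver, each with 41174 probes for genes. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The series title places the data in a study of how promoter sequence and development relate to gene expression.

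The B cell arrays were dimmer than the liver arrays. The 75th percentile of the processed signal was 58.8 ± 5.46 (SD, n = 2) in B cells and 440.4 ± 81.4 (SD, n = 3) in liver, and 41.1% ± 1.70 (SD, n = 2) of gene spots were well above background in B cells against 56.0% ± 3.72 (SD, n = 3) in liver. Spike-in controls, which are known RNAs added to each labelling, differed little between the groups. Over the 8 spike-ins measured on all arrays, B cells differed from liver by 0.07 ± 0.16 on the log2 scale (SD over spike-ins, not over arrays). Single arrays differed more, and liver 3 lay above liver 1 in all 8. The spike-in a135, for example, was at 8.65 and 8.60 in B cells and 8.35, 8.64 and 9.11 in livers 1 to 3. All values below are log2 signals relative to the 75th percentile of their own array, and differences are B cells minus liver. Each tissue lay on a slide and scan of its own, so slide and tissue cannot be told apart.

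**Figure D1:**
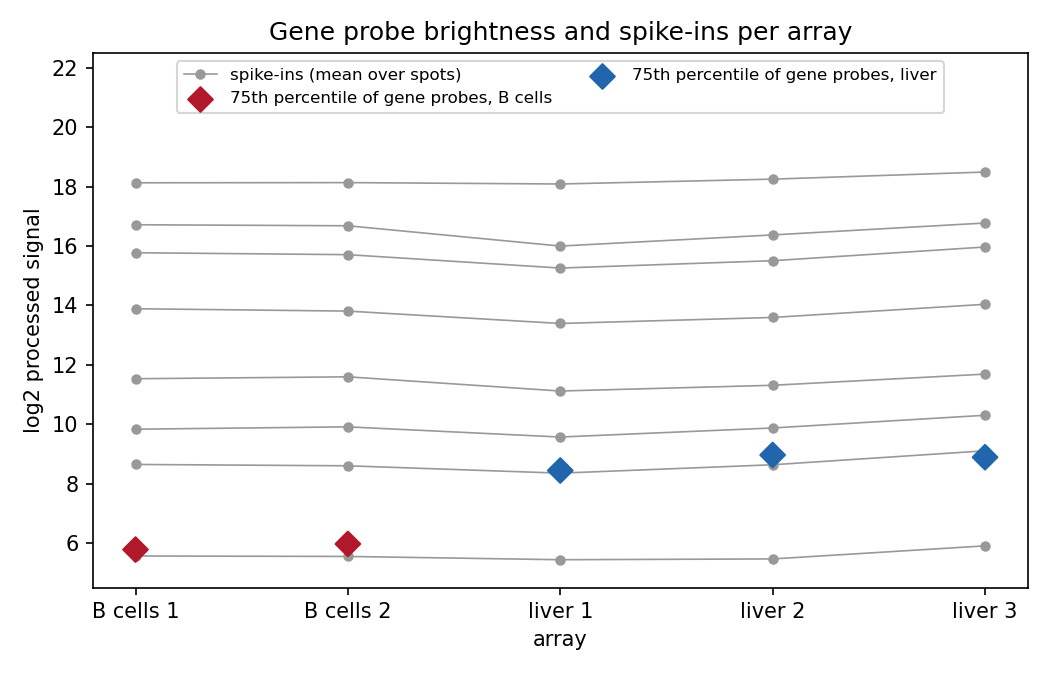
The log2 processed signal of each array (y axis) is shown for the 75th percentile of the gene probes (diamonds, red for B cells and blue for liver) and for 8 spike-ins (grey points joined by lines). The percentile was 54.9 and 62.6 in signal units on the B cell arrays and 348, 499 and 474 on the liver arrays, while the spike-ins differed between groups by -0.15 to 0.32 on the log2 scale.

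Arrays of the same tissue were close to each other. The Pearson correlation across the 15602 tested genes, which are not independent replicates, was 0.991 between the B cell arrays and 0.976 to 0.989 between liver arrays, against 0.481 to 0.493 between tissues. Of 27670 genes on the array, 10620 were detected in both tissues, 488 in B cells and on no liver array, and 3494 in liver and on no B cell array, while 9379 were detected on no array. The lowest signal that counts as detected differed between arrays. With 1 common floor of scaled signal, a rule added after the data were seen, the tissue-specific numbers became 1365 for B cells and 2076 for liver.

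Of the 15602 tested genes, 4499 were higher in B cells and 5717 higher in liver (limma, Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1), which is 65.5% of those tested. With normexp background correction and quantile normalization 46.8% were called, and at a minimum of 2 log2 units 38.7%. With signals of the dim tissue held at no less than the floor of detection, 1397 genes were at least 8-fold higher in B cells and 1547 in liver. In 2934 of the genes called higher in liver the representing probe was not well above background on either B cell array, and in 515 of those called higher in B cells it was not on any liver array. The scaled floor of detection was -2.59 and -2.76 on the B cell arrays, but -4.48, -4.52 and -3.91 on livers 1 to 3. A liver signal under the B cell floors can be called, though an equal B cell signal would not count as detected. Slc22a6, for example, was called higher in liver with -2.94, -3.75 and -3.59 there. The direction of such calls is not supported, and they were not counted separately. The share of calls that were higher in B cells was 44.0%, but 53.6% with normexp and quantile normalization, 57.7% among genes measured on all 5 arrays, and 7.41% when arrays were scaled to the spike-ins, a scaling added after the data were seen that moves the median of all genes from -0.26 to -3.22. Of the genes called higher in B cells, 1755 were called higher in liver under that scaling, and 31 of the 195 named genes changed sign. The directions given here are relative to the 75th percentile. Scaling to the median of each array moved it to -0.05.

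Among genes measured on all 5 arrays, Fcmr, an Fc receptor for IgM, had the largest excess in B cells, at 11.53 log2 units (SE 0.34). Cd79b, a signalling chain of the antigen receptor, was higher by 10.55 (SE 0.28) and Ighm, the heavy chain of IgM, by 10.13 (SE 0.30). Cd19, the protein used for purification, was 9.69 higher (SE 0.27, adjusted p = 1.4e-07). Its probe lies on chromosome 7 from 122505142 to 122505201 in the mm7 coordinates of the array design. Iglv1, Pou2af1, Mzb1 and Jchain completed the top 8 with differences of 9.55, 9.47, 9.45 and 9.36. Among genes whose probes were not well above background on any liver array, Tnfrsf13c, the receptor for the survival factor BAFF, was at least 1206-fold higher in B cells. Of this group, 2 kappa light-chain variable segments were at least 699-fold and 593-fold higher, and Fcer2a, the low-affinity IgE receptor CD23, at least 630.4-fold. Such bounds set the mean of the bright group against, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal.

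Lists of lymphocyte genes, fixed before the data were examined, were higher in B cells. All 19 members of the B cell identity list were called, over all genes and adjusted over the list alone, with a median difference of 8.75 (8.54 with 5 members at their bound; camera adjusted p = 7.5e-10). They included Ms4a1, which encodes CD20 and was at least 2042-fold higher with signal on 2 of the 3 liver arrays, and Cr2, the complement receptor CD21, at least 372-fold higher. Cr2 had 2 tested probes, and without B cells replicate 1 its difference was 3.38. With an estimated correlation the list had adjusted p = 0.145. Of 20 B cell receptor signalling genes 19 were higher, among them Card11 (149-fold), Ptprc, which encodes CD45 (138-fold), Blnk (101-fold) and Btk (79.3-fold), and the count adjusted over the list alone was also 19 (camera adjusted p = 1.1e-08, and adjusted p = 0.145 with an estimated correlation). Pik3ap1 was not called, with a difference of 0.50. All 12 genes of MHC class II presentation were higher, also adjusted over the list alone, with a median of 6.02. H2-Oa, a chain of the peptide-loading modulator H2-O, was higher by 9.08 and the invariant chain Cd74 by 7.31 (camera adjusted p = 1.5e-06, and adjusted p = 0.216 with an estimated correlation). H2-Ob was at least 305-fold higher, with signal on 1 of 3 liver arrays.

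Transcription factors and trafficking receptors of lymphocytes went the same way. Of 18 lymphoid transcription factors 16 were higher in B cells, 16 also adjusted over the list alone, with a median of 6.01, or 5.68 with bounded members at their bound (camera adjusted p = 2.6e-06, and adjusted p = 0.131 with an estimated correlation). Pax5, the factor that maintains B cell commitment, was at least 349-fold higher and Spib 379.8-fold higher. Klf2 was called lower by 2.95, but its probes disagreed, the other being higher in B cells by 3.92, and with the mean of its probes the difference was 0.49. All 16 genes of lymphocyte homing and cytokines were higher, also adjusted over the list alone, with a median of 7.51, or 6.56 with bounded members at their bound (camera adjusted p = 1.1e-08, and adjusted p = 0.169 with an estimated correlation). The chemokine receptor of B cell follicles, Cxcr5, was at least 1532-fold higher with signal on 1 of 3 liver arrays, and lymphotoxin beta, Ltb, was 491-fold higher. Of 9 plasma cell genes 4 were higher in B cells and 2 lower, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0884). Its median of 1.03 became -1.93 under spike-in scaling, where the list passed as higher in B cells relative to the other genes (adjusted p = 7.7e-04), whose median was then -3.22. Sdc1, which encodes the surface proteoglycan CD138, was lower in B cells by 3.47, and the secretory factor Xbp1 was not called with a difference of -0.23.

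In liver, secreted plasma proteins led. All 21 hepatocyte plasma protein genes were higher, also adjusted over the list alone, with a median difference of -13.11, or -11.25 with bounded members at their bound (camera adjusted p = 3.8e-10, and adjusted p = 0.131 with an estimated correlation). The largest bounds were those of Serpina3k, at least 6769-fold higher in liver, Ambp, at least 5661-fold, Fgb, a chain of fibrinogen, at least 5578-fold, and Serpina3m, at least 5408-fold. Alb, which encodes albumin, was at least 4288-fold higher in liver (adjusted p = 5.6e-07), with signal on 1 of 2 B cell arrays. Its probe lies on chromosome 5 from 90443687 to 90443746 (mm7). All 15 coagulation genes and all 16 complement genes were higher in liver, also adjusted over the list alone, with medians of -9.68 and -9.13, or -9.61 and -8.09 with bounded members at their bound. Prothrombin, F2, was at least 3530.3-fold higher, and the complement regulator Cfi at least 1439-fold. Their camera adjusted p were 1.0e-07 and 9.3e-08, and with an estimated correlation adjusted p = 0.131 and adjusted p = 0.169.

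Among genes measured on all 5 arrays, those with the largest excess in liver were Gsta3, a glutathione transferase, with a difference of -11.48 (SE 0.23), and Serpina1d, an alpha-1-antitrypsin gene, with -11.16 (SE 0.39). Akr1c6 (-10.25), Ephx2 (-10.18), Gnmt (-10.15), Cyp2d9 (-10.03), Serpinc1, which encodes antithrombin (-9.61), and Apof (-9.28) followed. In each the smallest liver value exceeded the largest B cell value, as the rule that chose these genes required.

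Metabolic lists of the liver were higher there in nearly all their members. All 25 drug metabolism genes, all 16 of bile acid synthesis and transport, all 22 of the urea cycle and amino acid breakdown, all 13 of glucose and fructose metabolism and all 19 of fatty acid oxidation were called, with the same counts adjusted over each list alone. Their medians were -10.41, -8.73, -9.66, -8.36 and -5.01, or -8.89, -6.70, -8.34, -7.0002 and -5.01 with bounded members at their bound. With an estimated correlation they had adjusted p = 0.169, 0.145, 0.145, 0.169 and 0.145, against camera adjusted p of 3.8e-10, 1.0e-07, 7.5e-10, 1.1e-06 and 3.6e-07. Examples were Adh1, an alcohol dehydrogenase (at least 2971-fold), Abcb11, the bile salt export pump (at least 1192-fold), Pah, phenylalanine hydroxylase (at least 1073-fold), Fbp1 of gluconeogenesis (at least 3618-fold), and Acox1 of peroxisomal oxidation (103-fold). Of 18 cholesterol synthesis genes 16 were higher in liver and 1, the regulator Srebf2, was higher in B cells by 1.69 (-1.27 under spike-in scaling), the same counts as adjusted over the list alone (camera adjusted p = 2.7e-04, and adjusted p = 0.227 with an estimated correlation). Hmgcr, the rate-limiting enzyme, was not called with a difference of -0.13. Of 17 hepatocyte transcription factors 15 were higher in liver and 1 in B cells, also adjusted over the list alone, with a median of -6.76, or -4.71 with bounded members at their bound (camera adjusted p = 3.6e-05, and adjusted p = 0.131 with an estimated correlation). Over the members well above background on all 5 arrays the median was -2.49 and the list did not pass (adjusted p = 0.0822). Hnf1a was at least 178-fold and Nr1h4, the bile acid receptor, at least 164-fold higher in liver. The exception was Hnf1b, higher in B cells by 1.45, whose other probe differed by -3.97. Without B cells replicate 1 or 2 that other probe represented it, at -3.47 and -4.48.

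**Figure D2:**
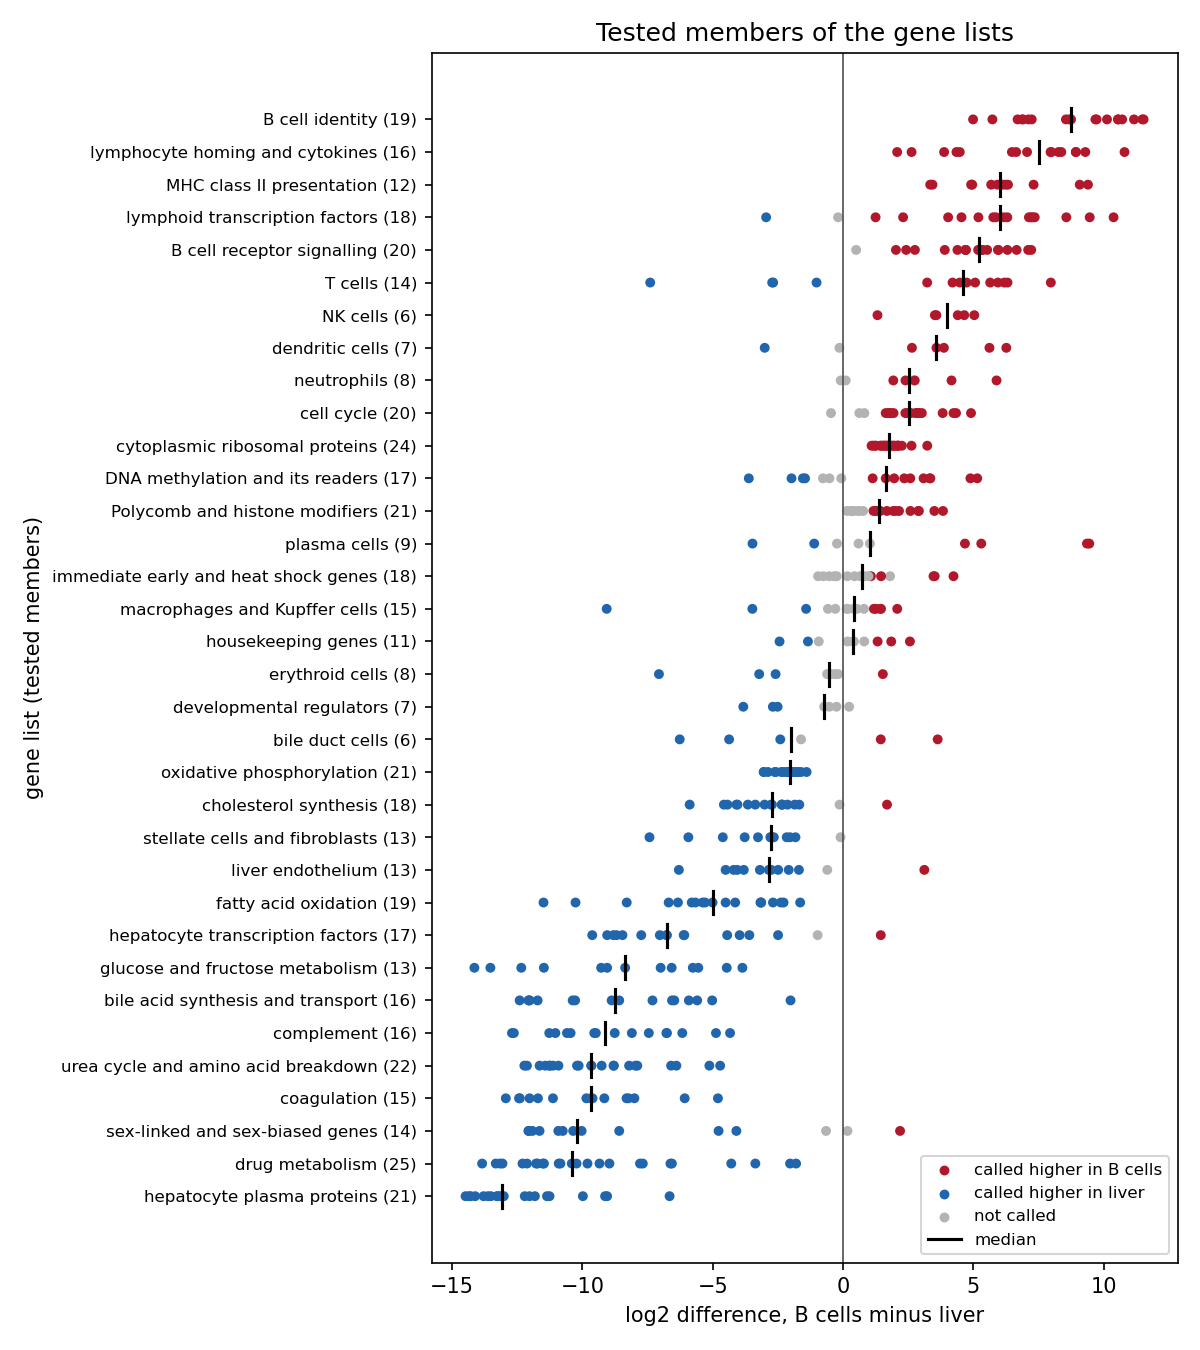
Each point is a tested gene of a list, placed by its log2 difference between B cells and liver (x axis), with lists in rows and the number of tested members in brackets. Black bars mark medians, which run from -13.11 for hepatocyte plasma proteins to 8.75 for B cell identity, and grey points were not called.

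Lists of general cell machinery split between the tissues. All 24 cytoplasmic ribosomal protein genes were higher in B cells, also adjusted over the list alone, with a median of 1.76 that became -1.20 under spike-in scaling. Rps19 differed by 3.23 and Rps15 by 2.63, or 0.27 and -0.33 under spike-in scaling (camera adjusted p = 3.6e-07, and adjusted p = 0.169 with an estimated correlation). Of 20 cell cycle genes 17 were higher in B cells, 17 also adjusted over the list alone, with a median of 2.54, or 2.46 with bounded members at their bound, that became -0.42 under spike-in scaling (camera adjusted p = 7.8e-06, and adjusted p = 0.234 with an estimated correlation). Mki67, the Ki-67 proliferation antigen, was 14.2-fold higher (a log2 difference of 3.82 that became 0.87 under spike-in scaling, where it was not called), the mitotic kinase gene Aurkb at least 10.9-fold, and Tyms was not called with -0.46. All 21 oxidative phosphorylation genes were higher in liver, also adjusted over the list alone, with a median of -2.05. Sdhb and Ndufv1 differed by -3.04 and -2.88 (camera adjusted p = 1.6e-05, and adjusted p = 0.234 with an estimated correlation). Of 11 housekeeping genes 3 were higher in B cells, including Actb by 2.57 (-0.39 under spike-in scaling), and 2 in liver, including Pgk1 with -2.44, the same counts as adjusted over the list alone. That list did not pass (camera adjusted p = 0.365), and its median of 0.39 became -2.57 under spike-in scaling.

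Genes that write or read DNA methylation went both ways. Of 17 tested, 10 were higher in B cells and 4 in liver, the same counts as adjusted over the list alone (camera adjusted p = 0.0884), with a median of 1.64 that became -1.32 under spike-in scaling, where the list passed as higher in B cells relative to the other genes (adjusted p = 0.0415). Uhrf1, which brings the maintenance methyltransferase to replicating DNA, was 29.6-fold higher in B cells, and Mbd4, a glycosylase that binds methylated DNA, at least 29.8-fold. Tet1, which oxidises methylcytosine, was at least 12.3-fold higher in liver with signal on 1 of 2 B cell arrays. Of 21 Polycomb and histone modifier genes 14 were higher in B cells and none in liver, 14 also adjusted over the list alone, with a median of 1.38 that became -1.57 under spike-in scaling (camera adjusted p = 5.1e-05, adjusted p = 0.0520 under spike-in scaling, and adjusted p = 0.131 with an estimated correlation). The Polycomb subunit Cbx7 was 14.3-fold and the deacetylase Hdac7 11.4-fold higher, and under spike-in scaling their differences of 3.84 and 3.51 became 0.88 and 0.55 and were not called, while Ehmt2 was not called with 0.41 (1.32 and called after quantile normalization). Of 24 developmental regulators on the array only 7 were tested, 3 of them higher in liver, also adjusted over the list alone, including Gata6 with -2.51 (camera adjusted p = 0.131). Their median of -0.73, or -0.43 with bounded members at their bound, became 0.74 with no filter on dim probes. That setting adds members below background, and 12 of the 24 were detected on no array, so the change of sign shows no direction. None of the 15 germline genes on the array was tested, and 12 were detected on no array. Of 18 immediate early and heat shock genes 5 were higher in B cells, also adjusted over the list alone, among them Btg2 by 4.24 and Nr4a1 by 3.47 (0.51 and not called under spike-in scaling; camera adjusted p = 0.0574). The list's median of 0.73 became -2.23 under spike-in scaling and 0.89 without B cells replicate 2. The list passed by camera without liver 2 (0.80, adjusted p = 0.0250), without liver 3 (0.85, adjusted p = 0.0421) and with the replicate block (0.85, adjusted p = 0.0369).

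Markers of cell types other than B cells were also measured on the B cell arrays. Of 14 tested T cell genes 10 were higher in B cells than in liver and 4 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.444 with an estimated correlation), with a median of 4.61, or 4.34 with bounded members at their bound. By camera the list did not pass after quantile normalization (adjusted p = 0.0502), with no filter on dim probes (adjusted p = 0.0966) or with only probes measured on all 5 arrays (adjusted p = 0.377). Cd2 was at least 226-fold higher with signal on 2 of 3 liver arrays, and Cd8a at least 45.3-fold with signal on 1 of 3. Among the 4 lower were Cd3e, at -2.68 with signal on all 5 arrays, and Zap70, at -2.93 to -2.49 with each array left out. The other probe of Cd3e was below background on all 5 arrays. Cd4 was called lower, at -1.02, from a probe below background on the B cell arrays. Its liver signals of -3.13 to -2.73 did not exceed the higher B cell floor of -2.59, so its direction is not supported. Itk was also called lower, by 7.40, from a probe that another of its probes contradicted with 2.53. Whether signal of such genes came from the B cells themselves was not tested. Of 10 natural killer cell genes on the array 6 were tested, and 3 were detected on no array. All 6 tested genes were higher, also adjusted over the list alone, including Klrd1 by 5.04, with a median of 3.99, or 3.48 with bounded members at their bound (camera adjusted p = 0.00318, and adjusted p = 0.328 with an estimated correlation). So were 5 of 7 dendritic cell genes, with 1 lower, and 5 of 8 neutrophil genes, the same counts as adjusted over the list alone, including Siglech at least 15.9-fold and Camp at least 12.8-fold (camera adjusted p = 0.0422 and 0.0193, and adjusted p = 0.234 and adjusted p = 0.203 with an estimated correlation). By camera the dendritic cell list did not pass after quantile normalization (adjusted p = 0.0590), with normexp (adjusted p = 0.0926) or with the mean of probes (adjusted p = 0.129). Nor did the neutrophil list with normexp background correction (adjusted p = 0.0659) or with only probes measured on all arrays (adjusted p = 0.172). The neutrophil median of 2.55, or 2.39 with bounded members at their bound, became -0.41 under spike-in scaling. Over the 68 markers of 9 other cell types that were well above background on both B cell arrays, replicate 1 was higher than replicate 2 by a median of 0.45, against 0.12 for the 19 B cell identity genes. Macrophage genes went both ways, 5 higher in B cells, including Marco by 2.08 (-0.88 under spike-in scaling), and 3 in liver, including the Kupffer cell lectin Clec4f, at least 160.1-fold, also adjusted over the list alone (camera adjusted p = 0.437). Their median was 0.41 (-2.55 under spike-in scaling) and their mean -0.36.

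Liver carried the markers of its own non-parenchymal cells. Of 13 endothelial genes 11 were higher in liver and 1, Pecam1, in B cells by 3.12 (0.16 and not called under spike-in scaling), and of 13 stellate cell and fibroblast genes 12 were higher in liver, the same counts as adjusted over the lists alone. Their medians were -2.85 and -2.78, or -2.75 and -2.72 with bounded members at their bound. Clec4g of the sinusoids differed by -6.30 and the matrix gene Dcn by -7.43 (camera adjusted p = 0.00439 and 0.00107, adjusted p = 0.0560 and adjusted p = 0.0227 under spike-in scaling, and adjusted p = 0.312 and adjusted p = 0.338 with an estimated correlation). Of 6 bile duct genes 3 were higher in liver, or 4 adjusted over the list alone, and 2 in B cells (camera adjusted p = 0.605), with Spp1 at least 72.5-fold higher in liver and signal on 1 of 2 B cell arrays. Of 8 erythroid genes 3 were higher in liver and 1 in B cells, also adjusted over the list alone (camera adjusted p = 0.315), with Alas2 at -7.06. The globin genes Hba-a1 and Hbb-bt were not called at -0.61 and -0.31, and without liver 2 they were called at -1.45 and -1.27. Of 3 tested platelet genes, too few for camera, Pf4 was higher in B cells by 2.45 (-0.51 under spike-in scaling), also adjusted over the list alone. Of 14 sex-linked and sex-biased genes 11 were higher in liver, among them Mup1, at least 3700-fold, with signal on 1 of 2 B cell arrays, and 1 in B cells, the Y-linked Kdm5d, by 2.19 (-0.77 under spike-in scaling), the same counts as adjusted over the list alone (camera adjusted p = 2.2e-04, and adjusted p = 0.270 with an estimated correlation). The Y-linked genes Ddx3y and Eif2s3y had signal on all 5 arrays and were not called, at -0.65 and 0.17.

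The liver samples differed among themselves in genes of the exocrine pancreas, the gland that secretes digestive enzymes. Of 27 such genes on the array, a list written after the livers had been compared, 27 were well above background in liver 2, 26 in liver 3 and 18 in liver 1. With the 9 genes below background in liver 1 held at its floor, liver 2 exceeded liver 1 by a median of at least 9.29 log2 units, and liver 3 exceeded it by at least 6.54 over 26 genes. The 2 genes named next were chosen after their values were seen. The elastase gene Cela3b had signals of -3.82, 8.76 and 6.19 in livers 1, 2 and 3, and the lipase gene Pnlip, below background in liver 1, had 7.86 and 5.24 in livers 2 and 3. Of 19 intestinal epithelium genes 15 had signal in liver 2, 10 in liver 3 and 7 in liver 1, and the bile duct keratin Krt19, called higher in liver (adjusted p = 0.0107, and 0.0904 with trend and robust settings), had -1.58, 2.66 and -1.35. Of the pancreas genes, 6 of 18 tested passed as higher in liver. Without livers 2 and 3 together, a choice made after the data were seen, 4542 genes were higher in B cells and 6374 in liver.

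**Figure D3:**
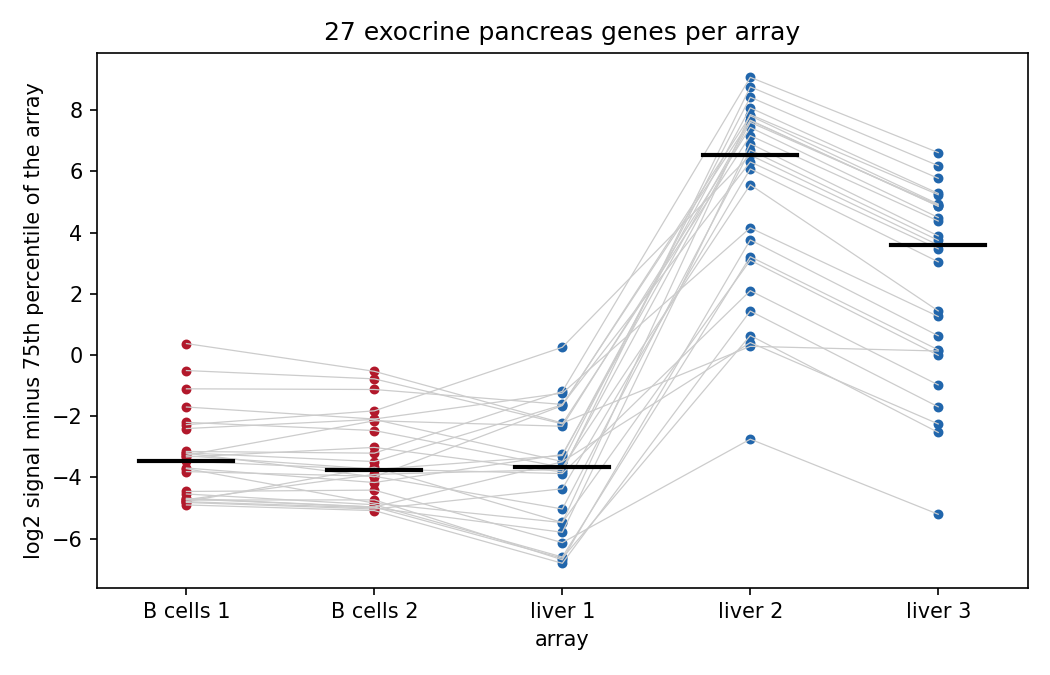
Signals of 27 exocrine pancreas genes (points, joined by grey lines per gene) are shown on each array as log2 signal minus the array's 75th percentile, with black bars for medians. The medians were -3.47 and -3.74 in B cells, -3.67 in liver 1, 6.53 in liver 2 and 3.59 in liver 3.

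All tests were two-sided moderated tests by limma, and precision is limited by the 2 and 3 arrays per tissue. No list passed by camera with an estimated correlation, the adjusted p ranging from 0.131 to 0.782. This also held for lymphoid and hepatocyte transcription factors and Polycomb genes, whose estimated correlations of -0.027, -0.011 and -0.028 lay under the preset 0.01. For these lists correlation between genes does not explain the lost call. In the simulation, with noise independent between genes, the camera adjusted p of the shifted list also rose, from 7.4e-49 to 0.00104. The setting thus weakens the test without such correlation. Its p-values therefore do not measure the strength of a list or its correlation alone. In 226 of 4952 genes with several tested probes the probes were called in opposite directions.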

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

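All tests in this part were chosen after the result was seen. The spike-in control spots enter the comparison of genes only where arrays were scaled to them. Dimmer spike-ins were left out. Over the 8 that were well above background on all spots of all 5 arrays, B cells differed from liver by a mean of 0.0673 (log2, SD 0.164 over spike-ins). The 75th percentile of gene spots differed by -2.89.

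The pattern is the lower signal of the B cell arrays. Weaker hybridisation or scanning of the B cell slide would dim the spike-ins by a comparable amount, and their difference of 0.0673 argues against it. A few genes taking most of the signal would leave the total signal alike, and that total differed by -3.14, with pairs of arrays between -3.33 and -2.87. Less labelled transcript per spike-in in the B cell samples stays open. Relative to the spike-ins 92.3% of 10588 genes measured on all 5 arrays were lower in B cells, but a lower percentile with alike spike-ins already fixes most of that share, so it decides nothing. The spike-ins were added to each labelling, so a labelling difference acting on all RNA alike would dim them too, and 0.0673 argues against it. A smaller RNA input, a smaller messenger share of total RNA in B cells and a labelling difference that spared the spike-ins were not tested separately. Tissue and slide go together in this design.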

How the results depend on the processing

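Settings with spike-in scaling, the percentile over probes measured on all arrays, the common detection floor and the fit without livers 2 and 3 were chosen after seeing the data, and causes were not tested unless stated. Promoter CpG class and both of its alternatives were not run, as no genome was used here. Leaving out saturated probes changed no call, and neither did the percentile over probes measured on all arrays for lists and named genes. Signal over background limits the B cell side most, since 2934 genes called higher in liver were below background there.

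Genes higher in B cells numbered 4437 to 4683 and genes higher in liver 5573 to 5904 with each array left out. Where a group then had 1 array, it was assumed to vary like the other. Genes higher in liver fell to 3388 with normexp and quantile normalization, against 3920 higher in B cells, and to 2558, against 3485 and on fewer tested genes, with only probes well above background on all 5 arrays, which also left 9 lists higher in liver. With no filter 12745 were higher in B cells and 5813 in liver. Genes below background on all arrays then enter, and after scaling their signals can lie higher in B cells. Lct, below background on all 5 arrays, was at -4.43 and -4.64 in B cells and -6.43, -6.58 and -5.93 in livers 1 to 3. The direction of calls on such signals is not supported. A minimum of 2 gave 2678 and 3354 by construction, and spike-in scaling gave 1028 and 12854. Detection on at least 1 array gave 5850 genes for liver alone, and the common floor 1365 for B cells and 2076 for liver.

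The replicate block gave 4492 genes higher in B cells and 5733 higher in liver. The numbers are not shown to pair the samples: the difference of the B cell arrays correlated at -0.028 with that of livers 1 and 2. With the block Hbb-bt was at 0.17 and Itga2b at 0.040, and the immediate early and heat shock list passed at 0.85.

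With an estimated correlation 0 lists passed in either direction by camera, with 10 at an unadjusted p under 0.05, against 32 by fry. Lists whose estimated correlation lay under the preset 0.01 lost their calls too (-0.027 for lymphoid and -0.011 for hepatocyte transcription factors, -0.028 for Polycomb genes). The loss is therefore not a measure of correlation between genes alone. The camera adjusted p of the simulated shifted list, with independent noise, also rose from 7.4e-49 to 0.00104 with this setting. The adjusted p was 0.131 for lymphoid and hepatocyte transcription factors, plasma proteins, coagulation and Polycomb genes, 0.145 for B cell identity, receptor signalling, bile acid, urea cycle and fatty acid oxidation genes, and 0.169 for homing, complement, drug metabolism, glucose and ribosomal genes. It was 0.203 for neutrophils, 0.216 for MHC class II, 0.227 for cholesterol, 0.234 for cell cycle, oxidative phosphorylation and dendritic cells, 0.270 for sex-linked genes, 0.312 for endothelium, 0.328 for NK cells, 0.338 for stellate cells and 0.444 for T cells. Fry gave adjusted p of 3.6e-04 for plasma cells, 0.00129 for DNA methylation, 0.00448 for developmental regulators, 0.0482 for immediate early genes, 0.00983 for erythroid cells and 0.00924 for bile duct cells, which camera did not call.

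Calls of lists ended at medians of 1.88 (dendritic cells) and 0.85 (neutrophils) with normexp, 4.76 (T cells) and 3.74 (dendritic cells) with quantile normalization, 4.77 and 3.76 with the series table, 2.65 (dendritic cells) with the mean of probes, and 4.203 (T cells), 3.58 (dendritic cells) and 2.32 (neutrophils) with no filter. With probes measured on all arrays they ended at -2.49 (hepatocyte transcription factors), 4.203 (T cells) and 1.93 (neutrophils). With no filter, which adds members below background on all arrays, the developmental list turned to 0.74. Without livers 2 and 3 the plasma cell (1.76), developmental (-1.18) and immediate early (1.41) lists passed. With each array left out, the dendritic cell median was 2.86 to 3.88 and the immediate early median 0.52 to 0.89. The first lost its call without B cells replicate 1, and the second passed without B cells replicate 2 (0.89), liver 2 (0.80) or liver 3 (0.85).

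Under spike-in scaling the lists of plasma cells (-1.93), cell cycle (-0.42), ribosomal proteins (-1.20), housekeeping (-2.57), DNA methylation (-1.32), Polycomb (-1.57), immediate early genes (-2.23), macrophages (-2.55) and neutrophils (-0.41) changed sign, and endothelium, at -5.81, lost its call (adjusted p = 0.0560), as did Polycomb genes (adjusted p = 0.0520). Camera sets a list against the other genes, whose median was then -3.22. Plasma cells (adjusted p = 7.7e-04) and DNA methylation (adjusted p = 0.0415) passed there as higher in B cells relative to those, and cell cycle (adjusted p = 3.4e-05), ribosomal proteins (adjusted p = 0.0324) and neutrophils (adjusted p = 0.00301) still did. Named genes that changed sign were Actb (-0.39), B2m (-2.57), C1qc (-2.42), Cd68 (-1.50), Csf3r (-2.85), Dnajb1 (-2.20), E2f1 (-2.33), Edem1 (-2.36), Ehmt1 (-2.65), Ehmt2 (-2.55), Eif2s3y (-2.79), Ep300 (-0.048), Gp1bb (-2.22), Hnf1b (-1.51), Hspa8 (-2.52), Ier2 (-1.50), Jarid2 (-0.070), Kdm5d (-0.77), Ltf (-0.26), Marco (-0.88), Pax2 (-2.72), Pf4 (-0.51), Pik3ap1 (-2.46), Rpl10a (-0.83), Rplp2 (-0.70), Rps15 (-0.33), S100a8 (-0.21), S100a9 (-0.56), Slc4a1 (-1.43), Srebf2 (-1.27) and Tbp (-1.11). Named genes that kept their sign and lost their call were Cbx7 (0.88), Clec10a (0.63), Egr2 (0.56), Epcam (0.67), Gadd45b (0.39), Gzma (0.62), Hdac7 (0.55), Itgax (0.91), Mki67 (0.87), Nr4a1 (0.51), Pecam1 (0.16) and Rps19 (0.27), and 18 others not called before were called higher in liver. Scaling to the spike-ins lowers every difference by 1 amount, which is the cause by construction.

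Other changes of sign were mostly in genes that were not called. Normexp gave Hba-a1 0.034, Hbb-bt 0.58, Hmgcr 0.16, Hnf1b -1.92, Itga2b 0.016, Slc40a1 0.17 and Xbp1 0.31. Quantile normalization gave Hba-a1 0.10, Hbb-bt 0.57, Hmgcr 0.070, Itga2b 0.086, Slc40a1 0.16 and Xbp1 0.17, and the series table gave 0.14, 0.51, 0.096, 0.12, 0.19 and 0.17 for these. Scaling to the median gave Hmgcr 0.078, Itga2b 0.13, Ngfr 0.12, Runx3 0.022 and Zbtb46 0.072. The mean of probes gave Hnf1b -1.26, Ier2 -0.42, Klf2 0.49 and Runx3 3.00, and the tested probes of Hnf1b, Klf2 and Ier2 had been called in opposite directions. Without livers 2 and 3 Ehmt1 was -0.12, Itga2b 0.18, Pax2 -0.32 and Zbtb46 0.11. Other calls of named genes ended with normexp for Creld2 (-0.23), Klra8 (0.97), Krt19 (-1.91), Ngp (0.97), Slc4a1 (0.66), Sox9 (-0.85), Tbp (0.77) and Ubc (-0.92), and with the mean of probes for Sdha (-0.64). The call of Creld2 also ended with quantile normalization (-0.16), the median (-0.89), the series table (-0.13), the block (-0.76), without B cells replicate 2 (-0.97) or liver 3 (-0.76) and without livers 2 and 3 (-0.64), and the last ended that of Sox9 (-1.40). Epcam lost its call without B cells replicate 1 (3.60) or liver 1 (3.095). Without B cells replicate 1 Cr2, which has 2 tested probes, was at 3.38 and still called. Calls of named genes were gained with normexp for C1qc (1.29), Dnajb1 (1.502) and Ehmt2 (1.32), with quantile normalization and the series table for C1qc (1.29 and 1.33), Dnajb1 (1.56 and 1.53), Edem1 (1.06 and 1.07) and Ehmt2 (1.32 and 1.31), with the median for Krt7 (-1.40) and Ltf (2.91), with probes measured on all arrays for Krt7 (-1.61), and with the mean of probes for B2m (1.97), Hhex (-1.21) and Zbtb46 (-1.38). With the block and without liver 3 they were gained for Hhex (-1.30) and Krt7 (-2.05), without B cells replicate 1 for Zbtb46 (-2.25), and without liver 2 for Hba-a1 (-1.45), Hbb-bt (-1.27), Hprt (-1.04) and Ltf (2.98). Without livers 2 and 3 they were gained for E2f1 (1.05), Hba-a1 (-1.18), Hbb-bt (-1.27), Hhex (-1.82), Hprt (-1.27), Ltf (3.85) and Neurog1 (-1.003). Trend and robust settings ended the calls of Krt19 (-4.37, adjusted p = 0.0904) and Epcam (3.63, adjusted p = 0.0986). Without B cells replicate 1 or 2, Cd8b1 was represented by another probe, at 0.60 and 0.95, and lost its call. With each array left out, Csf3r ranged from -0.26 to 0.46, Hbb-bt from -1.27 to 0.18, Hnf1b from -4.48 to 1.59, Itga2b from -0.22 to 0.040, Runx3 from -0.40 to 0.017 and Zbtb46 from -2.25 to 0.035.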

Other observations

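All tests in this part were chosen after the data were seen, and those of a shift of dim genes, of array scaling and of gene families were fixed before their own results were seen. Genes were grouped by the letters that open their symbol, which gave 151 families, of which 35 passed by camera and 0 with an estimated correlation (adjusted p = 0.749 or higher). Of 69 cytochrome P450 genes (Cyp) 64 were higher in liver and 1 in B cells, with a median difference of -5.34 with bounded members at their bound and -4.15 with normexp. All 14 carboxylesterase genes (Ces) and all 16 hydroxysteroid dehydrogenase genes (Hsd) were higher in liver, with medians of -7.77 and -5.17 at their bounds (-6.03 and -4.26 with normexp), as were 12 of 13 glucuronosyltransferase genes (Ugt), with -7.90 (-6.58 with normexp). All 14 kappa light-chain variable segments (Igkv) were higher in B cells, with a median of 7.62 at the bounds of 11 of them and 5.26 with normexp. Olfactory receptor genes (Olfr) passed too, with 160 of 201 called higher in liver and 6 in B cells. With 172 members at their bound, their median of -1.75 became -0.10. Of 20 Vmn genes 16 were called higher in liver and 1 in B cells, and with 17 at their bound the median of -1.44 became 0.42. These 2 families passed on signals near the floor, so a difference in expression is not shown.

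Smaller shifts ran through families of general machinery. Of 49 mitochondrial ribosomal proteins of the large subunit (Mrpl) 26 were higher in liver and 0 in B cells, with a median of -1.13 that became -0.51 with normexp, -0.61 with quantile normalization and -0.58 with the series table. Of 17 peroxins (Pex) 13 were higher in liver, with -1.99 (-1.46 with normexp). Of 46 cytoplasmic ribosomal genes (Rpl) 38 were higher in B cells and 1 in liver, with a median of 1.54 (1.90 with normexp) that became -1.42 under spike-in scaling. Zinc finger genes (Zfp) were higher in B cells in 103 and in liver in 37 of 256, with a median of 0.77 (0.53 with normexp) that became -2.19 under that scaling.

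Markers of other cell types were higher in B cells replicate 1 than in replicate 2. A candidate explanation is cells of other types left in the CD19 preparations. Its rule was written after the pattern was seen and uses the same markers, so the values describe the pattern between 2 single arrays. Of 68 markers 59 were higher in replicate 1, with a median of 0.454. The upper limit from 10000 random lists matched on expression was 0.0898. The medians were 0.58 for T cells, 0.53 for NK cells, 0.23 for macrophages, 0.60 for dendritic cells, 0.11 for neutrophils and 0.27 for erythroid cells, both under the limits of their own random lists (0.275 and 0.282), 0.47 for endothelium and 0.44 for stellate cells, and 0.89 for the 1 platelet gene. A shift of all dim genes is argued against by a median of 0.0130 for the random lists. B cell identity genes also passed their limit, 0.116 against 0.0902, while receptor signalling genes differed by -0.06, no biological explanation was tested, and selection on CD19 would remove most such cells.

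Exocrine pancreas transcripts were high in livers 2 and 3. Pancreas tissue or RNA in these samples is a candidate explanation. The list and its rule were written after the livers had been compared, so its values describe the pattern and do not test the explanation. Of the 27 genes 96.3% were well above background and at least 1 log2 unit higher than in liver 1 in both livers. Ctrc, Cela3b and Cpb1 were at 9.07, 8.76 and 8.42 in liver 2. Different scaling of the arrays is argued against by markers of 6 other tissues (46 genes), whose median difference was -0.0982 (SD 0.846) with most of them below background, or -0.14 (SD 0.615) over the 16 above background on all livers, and carry-over from the B cell arrays by 3.70% of the genes being brighter on a B cell array than in liver 2. Liver 1 itself had 18 of the 27 genes above background, 7 were above it on both B cell arrays, and liver 2 exceeded liver 3 by a median of 2.88 (SD 0.617). Whether tissue or RNA was carried, and at which step, stays open, and no biological explanation was tested.

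The other marker lists were mostly below background in 1 or more livers, so few differences were measured. Of 19 intestinal epithelium genes 15 were above background in liver 2, 10 in liver 3 and 7 in liver 1, and 26.3% met the same rule. Over those 15, liver 2 exceeded liver 1 by a median of at least 3.76. Of 13 islet genes 8 were above background in liver 2, and Ins1, Ins2 and Ppy were so in liver 2 alone of the livers, where they were at least 1.65, 3.73 and 2.06 higher than in liver 1. Of 10 stomach genes 1 met the rule, and over the 7 above background in liver 2 the median of liver 2 minus liver 1 was -0.53, with Tff2 and Gkn3 at 7.98 and 4.53. In liver 2, 3 of 10 kidney, 5 of 10 skeletal muscle, 4 of 7 lung, 2 of 8 brain, 2 of 5 adipose tissue and 5 of 6 testis genes were above background, and 0 in these lists met the rule. The rule asks for both livers 2 and 3, so signal in liver 2 alone cannot meet it. Over these genes, with liver 1 at no less than its floor, the medians of liver 2 minus liver 1 were -0.44, -0.05, 0.47, -0.02, 1.61 and -0.30. The liver also expresses some of the gut genes, such as Fabp2 at 6.75, 6.19 and 6.31 in livers 1 to 3.

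Among genes not tied to these lists, Cish, a cytokine-induced regulator of signalling, was at 5.05 in liver 1, 1.52 in liver 2 and 0.10 in liver 3, and the immediate early gene Egr1 was at -0.28, 4.37 and 2.50. Both were chosen after their values were seen.

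Pairs were made of called genes consecutive among the tested genes, ordered by position in the RefSeq table. Untested genes can lie between them. Of 5592 such pairs 59.0% were called in the same direction, against 51.2% on average and 53.5% at most in 10000 shuffles of the directions. Without pairs sharing the first 3 letters of their symbol, 55.8% of 4988 pairs still were, above the 53.7% of the highest shuffle. This argues against neighbours that share these letters as the whole cause. Related neighbours with unlike symbols were not removed. Genes are not independent replicates.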
